A study of Homo sapiens with 17 samples.

How the data were processed

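Gene expression was measured by bulk RNA-seq in 17 libraries of IMR-90 fibroblasts, grouped by the labels' titles and treatment into week 0 (untreated, n = 5), week 1 (n = 6) and week 4 (n = 6). Per the labels' protocols, RNA was purified on RNeasy columns with DNase and libraries were made with an Illumina RNA preparation kit. The authors deposited a file per library with raw gene counts by gene symbol, not normalized. Per the submitters' processing notes, HISAT2 2.0.5.2 and featureCounts 1.4.6 were used and the genome build is mm10, a mouse build. The deposited symbols are human, so the build behind the counts is unclear and no coordinates are given. The annotation, the strand setting and the treatment of multiply mapped reads are not given in the sources used here, so reads shared by near-identical genes or by overlapping genes on opposite strands cannot be assigned here.

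All files listed the same 41041 entries. The entry with no gene name, 0.221% to 0.289% of the counts per library, was left out of library sizes and tests, which left 41040 named genes. Totals over named genes were 77.2 to 102.8 M counts per library. The files of 4 libraries (week 0 replicates 5 and 6, week 1 replicates 1 and 2) were larger, because the deposited tables there also held a gene length, and the other 13 are called the smaller file class. Since the same genes were listed in both, no term for file class was fitted. No pair of libraries of a group differed by as little as sampling noise: the chi-square per gene was at least 7.65 over 40 pairs.

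Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group kept 16891 genes, TMM factors ran from 0.938 to 1.11, and a quasi-likelihood model with a mean per group was fitted to all libraries. The groups thus shared the same estimate of spread for each gene. The 3 comparisons were week 1 against week 0, week 4 against week 0 and week 4 against week 1, each with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. The standard error of a log2 fold change was its size over the square root of the F statistic. The biological coefficient of variation was 11.7%. Without scaling, the median log2 difference of all tested genes was -0.17, -0.18 and -0.02 in the 3 comparisons, and changes are given relative to the TMM scale. Levels of single genes are CPM on TMM-scaled library sizes, as mean ± SD over libraries, while marker sums and shares of counts are on library totals without TMM factors.

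Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, and 90 tests (30 lists in 3 comparisons) were adjusted together. The same lists were tested with an estimated correlation and with fry, whose test asks whether a list's genes move on balance one way and does not compare them with other genes. Of 31 lists fixed beforehand, the mitochondrially encoded genes could not be tested, because they had no counts. The lists reported were those of cyclin-dependent kinase inhibitors, DNA replication, mitosis, homologous recombination and crosslink repair, nuclear lamina and chromatin, inflammatory cytokines and chemokines, NF-kB genes, secreted growth factors, metalloproteinases, circulating senescence biomarkers, a broad senescence-associated list, interferon-stimulated genes, lysosome, extracellular matrix, contractile genes, cholesterol synthesis, anti-apoptotic genes, stress response, heat shock, respiratory chain, ribosomal proteins, histones, and markers of fibroblasts and of 6 other cell types. Library quality and marker sums, 11 measures in 3 comparisons, were compared by exact two-sided permutation tests of the difference of means, of which the smallest possible p is 0.0022.

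The lists, the tests, the alternatives and the genes to name were chosen before the data were examined, apart from those said to be chosen later. Named genes were a fixed set given whatever their result, the 5 that rose and fell most in each comparison (a mean of at least 5 CPM and no overlap between the libraries of the groups), and up to 2 rising and falling members per list with the smallest adjusted p. The part of the rule for lists held 168 genes, of which only some are given in the text. Certain genes and a gene list are not reported here, though they stayed in the tests and counts. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter (5 CPM in 5 libraries), a minimum fold change (glmTreat at a log2 fold change of 1), the replicate number as a block, only the groups compared, a file class term, the smaller file class alone, the most abundant genes left out, and each library left out in turn. Leaving out week 0 replicates 1 and 4, and a smooth correction of each library for gene length, and marker sums with TMM factors, were chosen after seeing the data. GC content came from reference transcripts for 99.4% of tested genes, and gene length from the files that hold it.

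The methods were tested on simulated counts for week 1 against week 0 (16774 genes, 200 of them changed). edgeR recovered 29 of 50 genes at the smallest simulated change, 44 at 1.5-fold, 49 at 2-fold and 50 at 4-fold. Camera called 0 of 84 tests of random lists, but the simulated genes were drawn independently, so correlation between genes was not tried. Comparisons against shared libraries were set beside 20 simulations of unchanged groups, and the call counts beside 100 of the possible splits of the same libraries. The samples of the labels' groups were all used.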

Results

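RNA-seq was carried out on IMR-90 cells, a diploid fibroblast line derived from human fetal lung, before and after treatment with etoposide, a topoisomerase II poison that causes DNA double-strand breaks. Untreated cells were collected as the week 0 group (n = 5 libraries). The other cultures received 20 µM etoposide for 48 h, were returned to medium without the drug and were harvested at week 1 (n = 6) or week 4 (n = 6). Each library held between 77.2 and 102.8 M counts assigned to named genes. Of 41040 named genes, 16891 had enough counts to be tested. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Untreated cells were sampled at week 0 only, so the comparisons with week 0 hold both treatment and time in culture.

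Fibroblast markers summed to more than the epithelial, endothelial, smooth muscle and pericyte, or leukocyte markers in all groups. Over 12 fibroblast markers the sum was 14937 ± 928 CPM (counts scaled to the library total, without TMM factors for these sums) at week 0, 21696 ± 260.4 CPM at week 1 and 24569 ± 397 CPM at week 4 (mean ± SD), most of it from the collagen gene COL1A2. The epithelial marker sum rose from 74.7 ± 2.73 to 258 ± 15.95 CPM at week 1 and stood at 209 ± 6.24 CPM at week 4, carried by the simple-epithelial keratins KRT18, KRT8 and KRT19. The endothelial marker sum was 99.5 ± 7.37, 68.1 ± 1.35 and 73.9 ± 8.87 CPM at weeks 0, 1 and 4, most of it from the receptor gene TEK, and the smooth muscle and pericyte sum was 776 ± 62.1, 521 ± 9.05 and 527 ± 9.36 CPM. Leukocyte markers summed to 1.38 ± 0.245, 2.38 ± 0.379 and 2.02 ± 0.327 CPM. The 10 most abundant genes took 10.99 ± 0.692%, 13.8 ± 0.242% and 15.6 ± 0.137% of the counts. Ribosomal protein genes took 4.70 ± 1.248% at week 0, with a wide spread, against 3.73 ± 0.169% and 4.08 ± 0.170% later. Week 0 replicates 1 and 4 held 6.38% and 5.62%, against 3.48% to 4.20% in the other week 0 libraries. Of 33 such comparisons, 23 passed an exact two-sided permutation test after adjustment. With TMM factors, as used for single genes, the epithelial sums were 68.5 ± 2.99, 265 ± 15.1 and 219 ± 8.70 CPM at weeks 0, 1 and 4, and 16 of the 21 marker sum comparisons passed against 16 without. The call differed from week 1 to week 4 for smooth muscle and pericyte markers, which then passed (adjusted exact p = 0.014), and for neural markers, which then did not (adjusted exact p = 0.10). The 13 mitochondrially encoded genes had a count of 0 in all 17 libraries, so their expression cannot be read from these counts.

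The comparison of week 1 with week 0 asks how the transcriptome of etoposide-treated cells differs from that of untreated cells soon after treatment. Proliferation genes fell together. All 32 DNA replication genes fell, as did all 33 mitotic genes, all 19 tested genes of homologous recombination and crosslink repair, and 17 of 18 genes of the nuclear lamina and chromatin. MKI67, a proliferation marker, fell from 410.4 ± 58.4 to 42.7 ± 4.62 CPM. RRM2, a subunit of ribonucleotide reductase, fell from 356 ± 13.6 to 43.3 ± 1.97 CPM, and MCM7, part of the replicative helicase, from 257 ± 13.2 to 38.7 ± 1.71 CPM. LMNB1, which encodes lamin B1, was 14.9-fold lower (log2 fold change -3.90 ± 0.08 SE, adjusted p = 1.0e-20). The chromatin proteins HMGB1 and HMGB2 were 4.83-fold and 9.59-fold lower at the transcript level. By camera, a competitive gene set test, the lists were called lower with adjusted p = 3.9e-23, 3.2e-24, 2.4e-13 and 1.1e-13, in the order given. With an estimated correlation between genes the adjusted p values were 0.0024, 0.017, 0.0089 and 0.0024.

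CDKN1A, the p21 inhibitor of cyclin-dependent kinases, went from 284 ± 14.2 to 2141 ± 53.7 CPM, a 7.53-fold rise (adjusted p = 1.7e-21). GDF15, a secreted stress-response factor, rose 12.1-fold and BTG2, an antiproliferative gene, rose 6.14-fold. The 6 tested cyclin-dependent kinase inhibitors went both ways, 3 up and 3 down, and as a list were not called. Besides CDKN1A, CDKN2B (p15) rose from 5.40 ± 0.556 to 18.7 ± 0.966 CPM and CDKN2A, the locus of p16 and ARF, from 9.24 ± 0.874 to 17.4 ± 1.10 CPM. CDKN2C (p18) fell from 39.2 ± 2.16 to 3.05 ± 0.407 CPM and CDKN1B (p27) from 37.9 ± 1.83 to 19.9 ± 1.10 CPM.

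Secreted and inflammatory genes moved less uniformly. Of 22 tested cytokines and chemokines, 11 rose and 5 fell, and the list was not called (adjusted p = 0.16). IL6 rose 4.06-fold to 27.6 ± 2.69 CPM, CCL2 rose 2.99-fold, CXCL8 (interleukin 8) rose 1.63-fold and IL32 rose from 4.32 ± 0.263 to 83.2 ± 4.03 CPM. CXCL12 and IL11 fell 7.69-fold and 5.21-fold. Among NF-kB feedback and target genes, 13 of 18 rose and 2 fell, with the adhesion molecule ICAM1 7.74-fold higher, and TNFAIP6, a secreted hyaluronan-binding protein, and BCL3 8.74-fold and 1.68-fold lower. Among secreted growth factors and their regulators, 22 of 33 rose and 9 fell. The growth factor HGF and the Wnt antagonist DKK1 fell 3.78-fold and 3.94-fold. Camera called the NF-kB list (adjusted p = 2.4e-04) and the secreted factor list (adjusted p = 6.2e-04) higher. Neither call held with an estimated correlation (adjusted p = 0.15 and 0.18). The 20 tested genes of circulating senescence biomarker proteins, of which 14 rose and 3 fell, were called higher by both (adjusted p = 9.9e-04, and 0.023 with an estimated correlation). A broad senescence-associated list of 104 tested genes, written from memory after SenMayo, held 54 that rose and 31 that fell (adjusted p = 0.025, and 0.27 with an estimated correlation). Metalloproteinases and their inhibitors were mixed, with 10 of 17 up and 5 down. The inhibitors TIMP1 and TIMP3 rose 2.71-fold and 4.54-fold, MMP3 fell 3.59-fold, and MMP1 stood at 164 ± 43.2 and 164 ± 2.64 CPM (adjusted p = 0.97). Without week 0 replicates 1 and 4, MMP1 was higher at week 1 by 0.30 on the log2 scale (adjusted p = 6.9e-05).

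Lysosomal genes rose, 22 of 29 up against 3 down, and the call held with an estimated correlation (adjusted p = 1.1e-05 and 0.030). PSAP, the saposin precursor, rose from 589 ± 34.3 to 1356 ± 21.9 CPM. GLB1, which encodes the lysosomal beta-galactosidase, rose from 67.9 ± 3.96 to 96.5 ± 3.54 CPM, a 1.42-fold change, and the cholesterol transporter NPC1 fell 2.82-fold. Of 25 cholesterol synthesis genes, 18 rose and 3 fell (adjusted p = 7.0e-04, and 0.072 with an estimated correlation), among them SREBF2, the transcription factor of the pathway, at 3.33-fold. Histone genes of the replication-dependent class went both ways, 12 up and 8 down of 22 (called higher, adjusted p = 0.023, and 0.27 with an estimated correlation). With upper-quartile scaling the adjusted p of the histone list was 0.051. H2BC21 rose from 4.29 ± 0.378 to 42.4 ± 1.69 CPM and H2BC12 from 6.54 ± 0.792 to 57.1 ± 2.45 CPM, values that are uncertain because histone genes have near-identical copies. Matrix genes split 13 up and 11 down of 26 and were not called. LOX, a collagen cross-linking enzyme, rose 3.82-fold, while elastin (ELN) and periostin (POSTN) fell 2.08-fold and 1.77-fold. Contractile genes were 8 up and 2 down of 15, stress response genes 9 up and 5 down of 16, heat shock genes 2 up and 5 down of 8 and respiratory chain genes 0 up and 16 down of 33, and none of these lists was called (adjusted p = 0.067, 0.15, 0.19 and 0.11).

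The largest rises under the naming rule were those of TMEM178B (0.388 ± 0.145 to 15.5 ± 2.15 CPM), PTCHD4, CCND2, HDAC9 and CPA4. CCND2, which encodes cyclin D2, rose from 4.39 ± 0.739 to 105 ± 7.81 CPM, and the carboxypeptidase gene CPA4 from 26.3 ± 1.43 to 547 ± 14.3 CPM. The largest falls under the rule were those of ACTC1, a cardiac actin (11.99 ± 1.07 to 0.436 ± 0.235 CPM), the EGF-family ligand AREG (21.8 ± 3.31 to 0.809 ± 0.266 CPM), SMIM43, the mitotic kinase NEK2 and the phosphatase CDKN3. In all, edgeR called 11305 of 16891 genes changed at an adjusted p under 0.05, 5565 up and 5740 down, and 3497 of these by more than 2-fold (1964 up, 1533 down). Of all 16891 tested genes, 8221 were called and had no overlap between the libraries of the groups. Chance alone leaves 0.433% of tested genes without overlap. Tested against a minimum of 2-fold, the call count was 2193. Camera called 12 of 30 lists, 8 higher and 4 lower, and 7 of these held with an estimated correlation. Adjusted over the list alone, the counts that rose and fell at week 1 were 13 and 3 for NF-kB genes, 10 and 6 for metalloproteinases, 12 and 7 for interferon-stimulated genes, 13 and 12 for matrix genes, 19 and 3 for cholesterol synthesis genes and 2 and 6 for ribosomal protein genes. The other lists had the counts given by adjustment over all genes.

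At week 4 the question is whether these differences from untreated cells were still present. Proliferation genes were still low: all 32 DNA replication genes, all 33 mitotic genes, all 19 recombination and crosslink repair genes and all 18 lamina and chromatin genes were below week 0. MKI67 was at 66.5 ± 10.1 CPM against 410.4 ± 58.4 at week 0, and LMNB1 at 18.4 ± 1.43 against 147 ± 8.26 CPM. The camera adjusted p values were 3.9e-23, 2.4e-24, 2.9e-13 and 6.5e-14, and 0.0024, 0.017, 0.0089 and 0.0024 with an estimated correlation. CDKN1A stood at 1276 ± 43.3 CPM, 4.49-fold above week 0. CDKN2A reached 28.8 ± 2.07 CPM (3.12-fold) and CDKN2B 30.8 ± 2.36 CPM (5.71-fold). The 6 tested kinase inhibitors again split 3 up and 3 down.

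Inflammatory and secreted genes at week 4 held 13 of 22 cytokines and chemokines above week 0 and 2 below (adjusted p = 0.023, and 0.35 with an estimated correlation, and 0.19 with a stricter filter on low counts). IL6 was at 27.2 ± 5.09 CPM, CXCL8 at 16.4 ± 3.67 CPM and CCL2 at 69.98 ± 10.1 CPM, which is 4.00-fold, 2.70-fold and 3.69-fold above week 0. CXCL12, at 46.7 ± 5.00 CPM, was 1.68-fold below week 0. It had risen 4.58-fold from week 1, between which times 11 genes of this list rose and 5 fell. Of 18 NF-kB genes 14 were higher and 2 lower (adjusted p = 4.7e-05, and 0.11 with an estimated correlation), including VCAM1 and TNFAIP3, a feedback inhibitor of the pathway, at 5.01-fold and 4.77-fold higher, and TNFAIP6 at 3.15-fold lower. Among secreted growth factors and regulators 21 were higher and 10 lower (adjusted p = 0.0032, and 0.24 with an estimated correlation). GDF15 was 8.59-fold and ANGPTL4 5.49-fold above week 0. The circulating biomarker list had 14 of 20 genes higher and 2 lower and was called by both versions of the test (adjusted p = 6.0e-05 and 0.0089). The broad senescence-associated list had 55 higher and 27 lower (adjusted p = 0.0086, and 0.21 with an estimated correlation). MMP1 was lower than at week 0, at 89.98 ± 8.01 against 164 ± 43.2 CPM (adjusted p = 4.1e-07), and MMP3 stayed low at 1.89 ± 0.960 CPM. The metalloproteinase list, 9 up and 5 down, was not called.

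Matrix genes were above week 0 at week 4, 21 of 26 up and 1 down (adjusted p = 2.0e-07, and 0.18 with an estimated correlation). LOX and its relative LOXL2 were 3.26-fold and 2.73-fold higher, and the proteoglycan gene BGN was 2.65-fold higher. Contractile and myofibroblast genes showed 9 of 15 up and none down (adjusted p = 0.025, and 0.42 with an estimated correlation, and 0.10 after a gene length correction). ITGA11, a collagen-binding integrin, and TGFBI were 2.16-fold and 1.52-fold higher. ACTA2, the smooth muscle actin gene, was at 492 ± 21.1 CPM at week 0 and 473 ± 45.4 CPM at week 4 (adjusted p = 0.40). Lysosomal genes were 19 up and 3 down of 29 (adjusted p = 7.8e-04, and 0.099 with an estimated correlation), with GLB1 1.22-fold higher. Cholesterol synthesis genes were 17 up and 4 down of 25 (adjusted p = 0.0038, and 0.11 with an estimated correlation). Genes of the unfolded protein and integrated stress response were 12 up and 3 down of 16 (adjusted p = 0.0080, and 0.27 with an estimated correlation), led by TRIB3 at 3.35-fold. Heat shock genes fell, 6 of 8 (adjusted p = 0.0057, and 0.093 with an estimated correlation), HSPH1 by 2.26-fold.

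Nuclear-encoded respiratory chain genes were lower at week 4, 27 of 33 down and none up, with a median log2 fold change of -0.46 (adjusted p = 5.6e-04, and 0.54 with an estimated correlation). UQCRFS1, the Rieske iron-sulfur subunit of complex III, went from 56.6 ± 6.91 to 33.5 ± 1.36 CPM. The size of this fall depended on the week 0 libraries: without week 0 replicates 1 and 4 the list's median was -0.21, though it was still called. The list was called in 26 of 27 other settings, the exception being the estimated correlation. Ribosomal protein genes were 3 up and 12 down of 40 at week 1 and 10 up and 2 down at week 4. As a list they were not called in either comparison (adjusted p = 0.69 and 0.24). Without week 0 replicates 1 and 4 they were called higher in both (adjusted p = 0.011 and 7.1e-07), and in the 13 libraries of the smaller file class they were called lower at week 1 (adjusted p = 0.0065). Week 0 in that class is replicates 1, 3 and 4 only, so both results turn on which week 0 libraries are kept. Pseudogene copies make single ribosomal protein genes uncertain.

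Under the naming rule the genes with the largest rises at week 4 were CLSTN2, a calsyntenin of synaptic membranes, CHI3L2, PTCHD4, L1CAM and TMEM178B. CLSTN2 was near the limit of detection at week 0, at 0.0329 ± 0.0511 CPM, and at 35.97 ± 2.22 CPM at week 4. CHI3L2, a chitinase-like secreted protein, went from 0.0788 ± 0.0827 to 18.4 ± 1.71 CPM and the adhesion molecule L1CAM from 0.802 ± 0.268 to 47.97 ± 3.64 CPM. The largest falls under the rule were in the cell division genes CDKN3, KIF20A, NEK2, CDC20 and CCNB1. KIF20A, a mitotic kinesin, fell from 233 ± 8.22 to 14.2 ± 2.49 CPM, and CCNB1 (cyclin B1) from 319 ± 74.8 to 20.5 ± 3.23 CPM. In all, 11414 of 16891 genes were called, 5722 up and 5692 down, with 3322 beyond 2-fold (2047 up, 1275 down). Of all 16891 tested genes, 8272 were called and had no overlap between the libraries (chance leaves 0.433% of tested genes without overlap). Against a minimum of 2-fold, 1991 genes passed (1270 up, 721 down). Camera called 17 of 30 lists (11 higher, 6 lower), of which 6 held with an estimated correlation. Adjusted over the list alone, the counts that rose and fell at week 4 were 22 and 10 for secreted growth factors, 10 and 5 for metalloproteinases, 56 and 27 for the broad senescence-associated list, 20 and 3 for lysosomal genes, 18 and 4 for cholesterol synthesis genes, 9 and 1 for ribosomal protein genes and 3 and 1 for leukocyte markers, and the other lists had those given by adjustment over all genes.

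**Figure D1:**
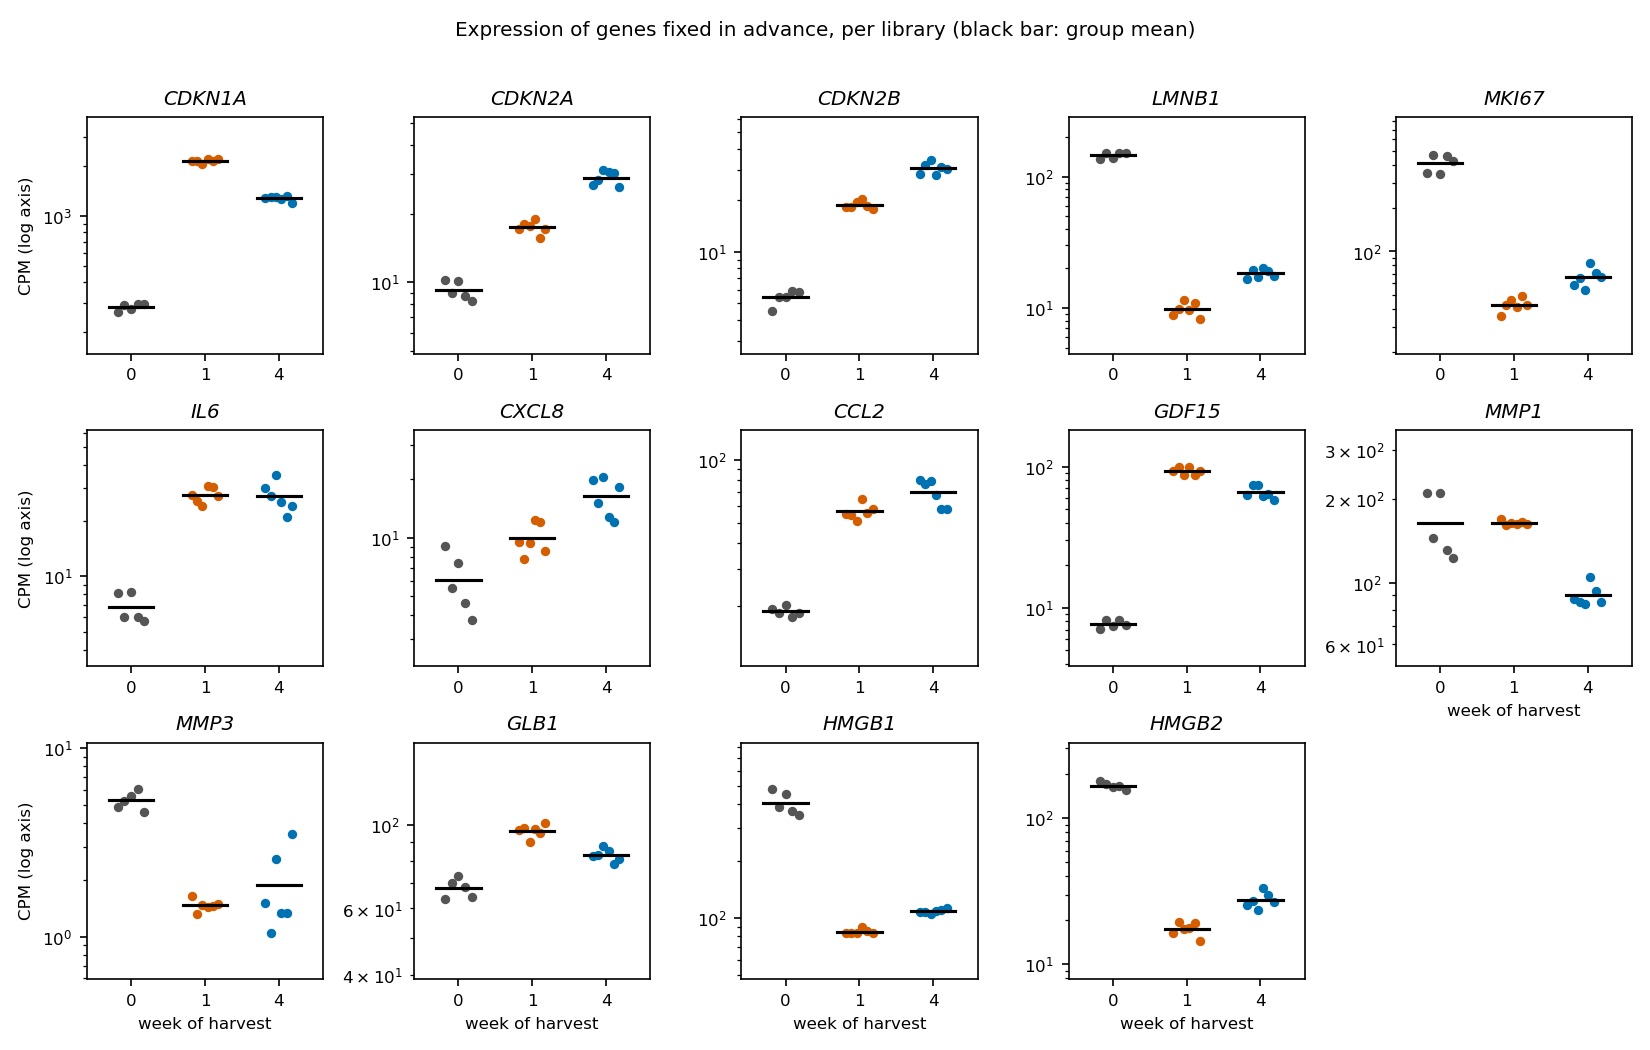
Expression of genes named whatever their result, in CPM on a log axis, against the week of harvest (0, 1, 4). Each point is a library and each bar the group mean; CDKN1A lies between 1194 and 2197 CPM in the treated libraries and between 264 and 296 CPM at week 0.

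**Figure D2:**
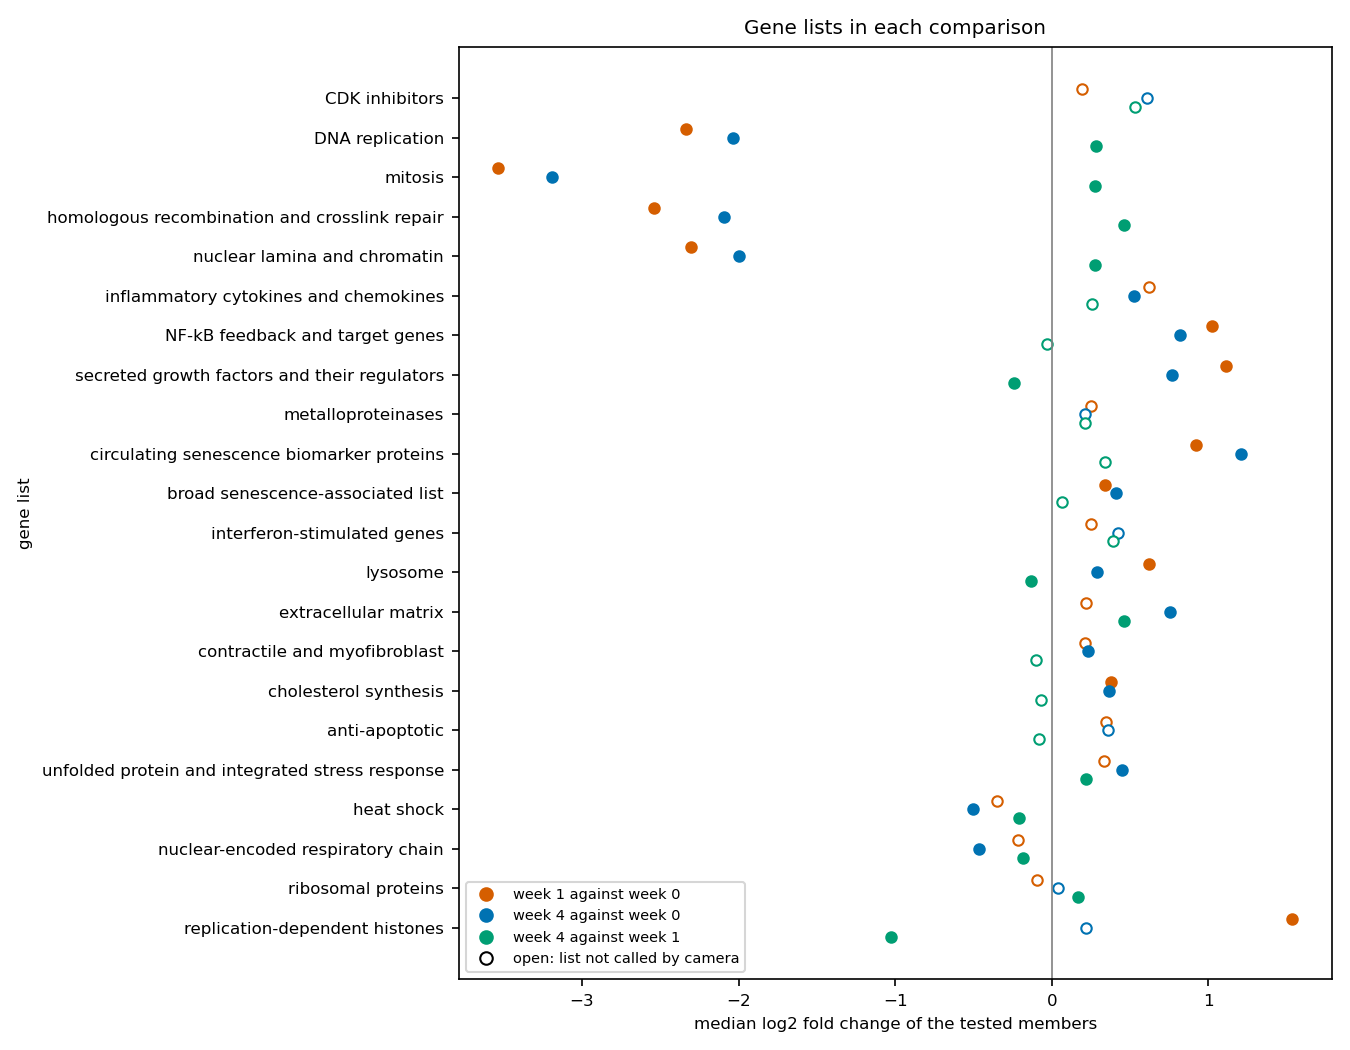
Median log2 fold change of the tested members of the reported gene lists, cell type markers aside, in the 3 comparisons, with filled points where camera called the list at an adjusted p under 0.05 and open points where it did not. The proliferation lists lie lowest against week 0 and above 0 in the comparison of week 4 with week 1.

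The comparison of week 4 with week 1 asks what changed between the treated time points. The proliferation lists rose from their week 1 level, 23 of 32 DNA replication genes, 18 of 33 mitotic genes (1 fell, AURKA), 16 of 19 recombination and crosslink repair genes, and 13 of 18 lamina and chromatin genes (1 fell, LMNA). Camera called all 4 higher (adjusted p = 1.1e-05, 7.8e-04, 2.4e-04 and 7.3e-04), and none held with an estimated correlation (adjusted p = 0.11, 0.40, 0.16 and 0.099). LMNB1 rose 1.87-fold to 18.4 ± 1.43 CPM and MKI67 rose 1.56-fold. The fall of AURKA did not pass in the 13 libraries of the smaller file class (adjusted p = 0.061). CDKN1A fell 1.68-fold, whereas CDKN2A and CDKN2B rose 1.65-fold and 1.65-fold.

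Replication-dependent histone genes fell, 15 of 22 and none up (adjusted p = 5.8e-09, and 0.0089 with an estimated correlation). H2BC21 and H2BC12 fell 2.85-fold and 2.14-fold, with the same reservation about near-identical copies. Matrix genes rose, 20 of 26 up and 2 down (adjusted p = 8.6e-11, and 0.099 with an estimated correlation), with tenascin C (TNC) going from 1124 ± 74.00 to 3366 ± 284 CPM and ELN from 159 ± 13.96 to 408 ± 40.6 CPM. Secreted growth factors were 20 down and 10 up of 33, called lower (adjusted p = 0.025, and 0.35 with an estimated correlation). With the stricter filter and with the length correction the adjusted p of this list was 0.058 and 0.051. Lysosomal genes were 13 down and 5 up of 29 (adjusted p = 0.0092, and 0.19 with an estimated correlation). The stress response list had 9 genes up and none down (adjusted p = 0.0023, and 0.21 with an estimated correlation). Heat shock genes showed 4 down of 8 (adjusted p = 0.0032, and 0.072 with an estimated correlation), and respiratory chain genes 16 down of 33 (adjusted p = 7.8e-04, and 0.55 with an estimated correlation). Ribosomal protein genes showed 9 up of 40 (adjusted p = 0.0042, 0.66 with an estimated correlation and 0.11 with a file class term).

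The largest rises from week 1 to week 4 under the naming rule were those of CLSTN2, CHI3L2, SAMD11, CHRDL2 and TIE1. CHRDL2, a secreted antagonist of bone morphogenetic proteins, rose from 10.99 ± 0.911 to 60.9 ± 9.66 CPM, and SAMD11 from 3.30 ± 0.337 to 19.3 ± 2.11 CPM. The endothelial receptor gene TIE1 rose from 1.71 ± 0.181 to 9.19 ± 1.28 CPM. The largest falls under the rule were those of SERPINB2, H2BC21, SERPINB7, RRAD and KCNJ2, of which SERPINB2, plasminogen activator inhibitor 2, went from 31.2 ± 0.935 to 9.68 ± 1.34 CPM. In all, 6835 genes were called, 3685 up and 3150 down, but only 697 beyond 2-fold (505 up, 192 down). Against a minimum of 2-fold, 150 genes passed, 132 up and 18 down. IL6 was at 27.6 ± 2.69 and 27.2 ± 5.09 CPM at weeks 1 and 4 (adjusted p = 0.89). Camera called 13 of 30 lists (7 higher, 6 lower), of which 2 held with an estimated correlation. Adjusted over the list alone, the counts that rose and fell from week 1 to week 4 were 19 and 1 for mitotic genes, 14 and 1 for lamina and chromatin genes, 6 and 8 for NF-kB genes, 10 and 21 for secreted growth factors, 41 and 37 for the broad senescence-associated list, 5 and 14 for lysosomal genes, 21 and 2 for matrix genes, 6 and 7 for contractile genes, 10 and 0 for stress response genes, 0 and 5 for heat shock genes, 5 and 0 for ribosomal protein genes, 6 and 2 for fibroblast markers, 2 and 3 for epithelial markers and 2 and 2 for endothelial markers.

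Most genes that differed from week 0 at week 1 differed the same way at week 4. The comparisons shared 9139 genes called in the same direction, 4530 up and 4609 down, and 303 called in opposite directions. Independent lists of these sizes would share 3819 in the same direction and 3819.8 in opposite directions. Because both comparisons use the same week 0 libraries, 20 simulations of unchanged groups were run. All 17 libraries were drawn anew from the week 0 means, with the same spread per gene in all groups. The simulations gave a correlation of fold changes across genes of 0.539. Their mean of 0 shared calls follows from holding no changed genes, so it is no yardstick for the overlap. The observed correlation was 0.902, with a covariance of 1.07 against 0.0225 simulated, a difference of 1.05. With the week 0 libraries divided between the comparisons, 3 for one and 2 for the other, the 10 possible divisions gave 7745 to 7897 genes in the same direction, 212 to 899 in opposite directions and correlations of 0.783 to 0.828.

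**Figure D3:**
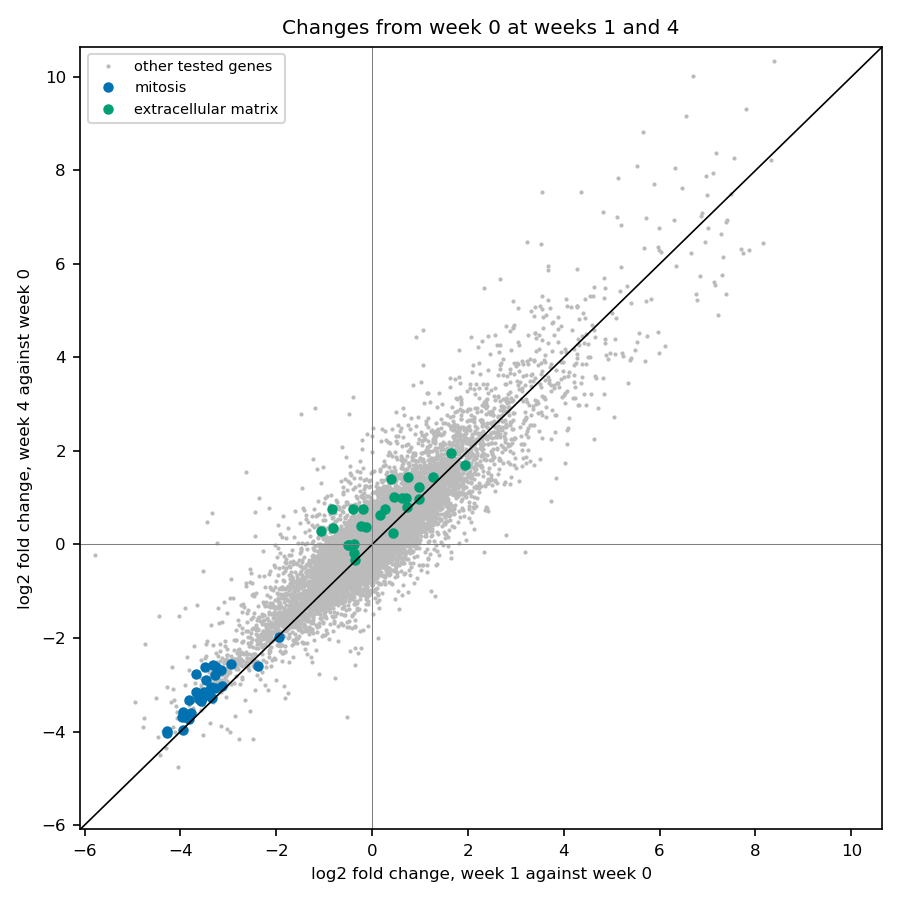
Log2 fold change at week 4 against that at week 1, both relative to week 0, for tested genes (grey) with mitosis genes (blue) and matrix genes (green) marked; the diagonal marks equal change. Mitosis genes lie in the lower left.

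Of the 11305 genes called at week 1, 3703 changed back between weeks 1 and 4, 1839 that had risen and 1864 that had fallen. Back means against the direction of the week 1 change. It includes genes that passed week 0 to its other side, such as the matrix genes ELN, POSTN and TNC. A further 1595 moved on in the same direction, and 6007 were not called again, which is not evidence that they stayed the same. Independent lists would give 2290.1 and 2285. The comparisons share the week 1 libraries, which draws the correlation below 0 with no effect at all. The observed correlation was -0.245, with a covariance of -0.130, against -0.483 and -0.0195 in the simulations of unchanged groups. The mean of 0 such calls there follows from the simulations holding no changed genes. With the week 1 libraries divided into sets of 3, the 20 divisions gave 2784 to 2929 genes that changed back and 963 to 1346 that moved on. Among the lists, 23 of 32 changed DNA replication genes and 16 of 19 recombination and crosslink repair genes moved back, and none moved on. Of 33 mitotic genes 18 moved back and 1 on. In other lists, of 16 changed respiratory chain genes 0 moved back and 7 on, of 14 stress response genes 3 back and 5 on, of 21 cholesterol synthesis genes 3 back and 3 on, and of 24 matrix genes 11 back and 9 on. These differences between lists were not tested.

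Some lists were called in none of the 3 comparisons. Anti-apoptotic genes rose and fell as 5 and 3 of 9 at week 1, 6 and 3 at week 4, and 1 and 3 from week 1 to week 4. BCL2L1, which encodes BCL-xL, was 2.11-fold above week 0 at week 1 and 1.37-fold at week 4. The members with the smallest adjusted p went both ways. BIRC3 and CFLAR were 4.86-fold and 1.79-fold above week 0 at week 1, and 4.22-fold and 1.54-fold at week 4. BCL2 and BIRC2 were 2.75-fold and 1.55-fold below week 0 at week 1, and 2.85-fold and 1.44-fold at week 4. Interferon-stimulated genes rose and fell as 11 and 7 of 26, 14 and 3, and 10 and 2, with IFIT2 4.80-fold higher and OAS3 3.65-fold lower at week 1. Of 12 tested fibroblast markers, 3 rose and 7 fell at week 1, 4 and 5 at week 4, and 5 and 2 between them. Of 7 tested epithelial markers, 4 rose and 2 fell at week 1, 4 and 1 at week 4, and 1 and 3 between them. Of 5 tested endothelial markers, 3 rose and 2 fell at week 1, 3 and 2 at week 4, and 1 and 2 between them. Of 4 tested leukocyte markers, 2 rose and 0 fell at week 1, 3 and 0 at week 4, and 1 and 1 between them. Of 8 tested smooth muscle and pericyte markers, 3 rose and 3 fell at week 1, 3 and 3 at week 4, and 4 and 2 between them. Of 3 tested adipocyte markers, 1 rose and 1 fell at week 1, 1 and 0 at week 4, and 1 and 0 between them. Of 5 tested neural markers, 2 rose and 0 fell at week 1, 2 and 1 at week 4, and 1 and 1 between them. The list's median, mean and test differed in sign for smooth muscle and adipocyte markers at week 1, histones at week 4, and the NF-kB, contractile and neural lists between weeks 1 and 4.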

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

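The test of gene length for the spread of the week 0 libraries was chosen after that spread was seen, and the gene length correction and leaving out week 0 replicates 1 and 4 were also chosen after the data were seen. Single libraries far from the rest of their group were sought over 279 groups of values, 82 named genes and 11 quality measures in 3 groups, and 18 stood apart (6.45%), where chance gives about 1 in 20. Of these, 6 were in week 4 replicate 6. In week 0 replicate 1, TEK stood at 71.2 CPM against 85.4 to 88.1 CPM in the others of its group. In week 0 replicate 6, CDC20 stood at 209.8 CPM against 231 to 238 and CLSTN2 stood at 0.122 CPM against 0 to 0.0231 CPM in the others of its group. In week 1 replicate 1, ITGA11 stood at 193 CPM against 206 to 213 CPM in the others of its group. In week 1 replicate 3, BCL2L1 stood at 76.1 CPM against 85.7 to 88.8 CPM in the others of its group. In week 1 replicate 4, HMGB1 stood at 89.5 CPM against 83.1 to 85.3, TIMP1 stood at 4086 CPM against 3537 to 3709 and TNFAIP6 stood at 1.45 CPM against 0.763 to 0.997 CPM in the others of its group. In week 4 replicate 1, OAS3 stood at 14.8 CPM against 8.71 to 10.1 CPM in the others of its group. In week 4 replicate 2, BCL3 stood at 23.9 CPM against 21.9 to 22.6 and LOX stood at 1726 CPM against 1858 to 1922 CPM in the others of its group. In week 4 replicate 6, AREG stood at 10.5 CPM against 2.40 to 4.24, CDKN1A stood at 1194 CPM against 1273 to 1318, IL11 stood at 35.5 CPM against 20.9 to 22.6, KRT8 stood at 60.1 CPM against 44.7 to 48.1, RRAD stood at 3.22 CPM against 5.62 to 6.44 and TNFAIP6 stood at 3.70 CPM against 2.31 to 2.67 CPM in the others of its group. In week 0 replicate 1 the entry with no gene name took 0.289% of the counts, against 0.237% to 0.251% in the other week 0 libraries.

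The week 0 libraries differed from each other more than those of the treated groups. Over 10118 genes with a mean of at least 5 CPM, the variance of log2 values within a group was 0.0398 at week 0, 0.0109 at week 1 and 0.0133 at week 4, and week 0 replicates 1 and 4 held 33.5% and 22.9% of the week 0 squared deviations. Thinning to the smallest week 0 total left 100.2% of the squared deviations. The week 0 totals were close, at 80.3 to 96.0 M counts, so thinning could remove little and cannot decide on depth. GC content is argued against as the main source, since a trend on it took out 7.18%. A trend on gene length took out 15.4%, too much to exclude it and too little to account for most of the spread. No biological explanation was tested, because the labels give nothing that differs among the untreated libraries.

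Nuclear-encoded respiratory chain genes fell at week 4 against week 0, with a median log2 fold change of -0.46. Gene length is argued against, since 95.4% of the median was left after the length correction. Without week 0 replicates 1 and 4, 44.4% was left, with a median of -0.21 and 3 genes up and 23 down of 33. Camera still called the list lower there. Those libraries may account for part of the fall, and a change with etoposide or with time in culture stays open and untested.

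Genes responded differently at the treated times. Between weeks 1 and 4, 6835 genes differed, and 303 genes were called in opposite directions against week 0. Examples called on opposite sides of week 0 at the treated times were ELN, POSTN, TIE1 and TNC, with log2 fold changes of week 4 over week 1 of 1.36, 1.17, 2.42 and 1.58. A chance division of these libraries is argued against by the splits. In each comparison 100 of 462 possible splits were run, and 1 gave as many calls, the real one included. The real counts were 11305, 11414 and 6835, and the highest others 9402, 9542 and 1864, with a median of 0. The splits treat the libraries as independent, which the labels do not show, so a difference between the groups' cultures would look the same.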

How the results depend on the processing

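Leaving out week 0 replicates 1 and 4, the gene length correction and marker sums with TMM factors were chosen after the data were seen. The counts of called genes in the 3 comparisons stayed within 1.5 times of those reported under every setting but a minimum of 2-fold, which gave 2193, 1991 and 150 by its own construction. The groups shared the same spread per gene, though week 0 varied more. The p-values against week 0 may thus be too small, and those of week 4 against week 1 too large. With only the 2 groups compared the counts were 10777, 10867 and 8268. Without week 0 replicates 1 and 4 they were 11296, 11299 and 8310. With each library left out in turn the counts ran from 10981 to 11372, 11015 to 11356 and 6218 to 7308, and list calls from 42 to 45. Of 90 list tests 42 were called, 15 with an estimated correlation and 76 with fry, which asks another question. With the replicate number as a block the counts were 11096, 11180 and 6669, with 43 list calls, the further one being interferon-stimulated genes from week 1 to week 4 (adjusted p = 0.033). Same-numbered libraries did not deviate together (r from -0.0383 to 0.0671 over 16 pairs), and 1 of 17 correlated best with its own number, so the numbers were not taken as pairs. The ribosomal protein list turned from lower (not called) to higher at week 1 without week 0 replicates 1 and 4 (adjusted p = 0.011, range over its settings 0.0065 to 0.94), and the cause was not tested. For the 82 genes of the comparisons, 246 results, none turned its direction with a call, 153 kept direction and call under all settings, 85 lost the call against a minimum of 2-fold, and 8 gained a call under some setting. The genes named only among other observations, and BCL2, BIRC2, BIRC3 and CFLAR, were not run through these settings. Apart from that minimum and single libraries, calls ended for AURKA, KIF20A and TEK from week 1 to week 4, in the smaller file class alone. Calls were gained without week 0 replicates 1 and 4 for LMNA, MMP1 and TGFBI at week 1 and KRT8 and NPC1 from week 1 to week 4 (log2 fold changes -0.15, 0.30, -0.15, 0.15 and 0.11), with the length correction for LMNA and TGFBI at week 1 (-0.17 and -0.14), and with only the 2 groups compared for BTG2 from week 1 to week 4 (-0.10). Single libraries left out changed the call of TGFBI (week 0 replicate 1), NEK2 (week 4 replicate 1), TEK (week 4 replicates 2 and 3), KIF20A (week 4 replicates 4 and 5) and IL11 (week 4 replicate 6), to log2 fold changes of -0.12, 0.47, 0.18 and 0.17, 0.19 and 0.20, and -0.32. Leaving out 1 library made 14 further list calls and ended none. These were ribosomal proteins at week 4 against week 0 (without week 0 replicate 1 or 4, adjusted p = 0.017 and 0.0498), contractile genes at week 1 (without week 0 replicate 5 or week 1 replicate 5, 0.045 and 0.04998), respiratory chain genes at week 1 (without week 0 replicate 5 or 6, 0.034 and 0.015), and interferon-stimulated genes from week 1 to week 4 (without week 0 replicate 1, 5 or 6, 0.045, 0.049 and 0.049; week 1 replicate 3 or 5, 0.035 and 0.015; week 4 replicate 2, 3 or 4, 0.039, 0.034 and 0.032). In the smaller file class alone, where week 0 is replicates 1, 3 and 4, respiratory chain genes were called lower at week 1 (adjusted p = 4.0e-04). Over all settings, fry included, the adjusted p ran from 4.0e-04 to 0.94 for respiratory chain and 3.8e-07 to 0.52 for contractile genes at week 1, 7.1e-07 to 0.85 for ribosomal proteins at week 4 against week 0, 0.0042 to 0.53 for interferon-stimulated genes from week 1 to week 4, 1.6e-12 to 0.27 for histones at week 1, 1.3e-07 to 0.35 for cytokines at week 4 against week 0, and 0.0016 to 0.35 for secreted factors and 1.4e-06 to 0.66 for ribosomal proteins from week 1 to week 4. Of 50 genes simulated with a 1.5-fold change at this depth 44 were recovered for week 1 against week 0, so smaller changes can be missed. Only 200 of 16774 simulated genes were changed, against 11305 of 16891 called here, so recovery in the real comparison may differ.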

Other observations

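The list of hypoxia-inducible factor (HIF) targets and the genes named here were chosen after the data were seen, as were the tests of time in culture, of gene length and without week 0 replicates 1 and 4. HIF targets, genes induced by low oxygen among which are many of glycolysis, stood above week 0 in the treated cells, and 3 of the 36 (LOX, ANGPTL4 and VEGFA) also belong to other lists. Of 36 tested members, 35 rose and 0 fell at week 1, 36 and 0 at week 4, and 24 and 4 from week 1 to week 4, with median log2 fold changes of 1.23, 1.52 and 0.25. Because the list was chosen on these data, no test of it as a set is given. CA9, a carbonic anhydrase, went from 1.17 ± 0.149 to 9.68 ± 0.883 and 38.8 ± 2.93 CPM, and NDRG1 from 109 ± 6.29 to 409.7 ± 8.83 and 519.6 ± 34.8 CPM. Among glycolytic members PGK1 went from 678 ± 170.4 to 1504 ± 59.5 CPM at week 4, while ENO1 was at 2479 ± 129 and 2478 ± 83.4 CPM at weeks 0 and 1.

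For the rise of HIF targets at week 4, gene length is argued against as the whole cause, since 92.5% of the list's median was left after the length correction, and so are week 0 replicates 1 and 4, since 100.5% was left without them. Time in culture rather than etoposide may account for the rise and cannot be told apart from treatment, because 0 untreated libraries of week 4 were analysed here. Cell density and oxygen in the dishes were not tested.

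Among genes called in opposite directions at weeks 1 and 4, MFAP4, a microfibril-associated glycoprotein, was at 148 ± 10.8, 77.5 ± 3.54 and 303 ± 32.1 CPM at weeks 0, 1 and 4. The natriuretic peptide clearance receptor gene NPR3 was at 53.9 ± 7.06, 29.6 ± 3.21 and 113 ± 14.7 CPM. The ubiquitin hydrolase gene UCHL1 went the other way, at 460.5 ± 80.8, 701 ± 21.9 and 358 ± 24.8 CPM, as did the kinase gene MAP2K3, at 99.8 ± 7.50, 148 ± 4.49 and 74.7 ± 7.26 CPM.

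Some entries with near-identical copies elsewhere had values that differed widely between libraries of a group. The pseudogene EEF1A1P19 ranged, without TMM factors, from 1.31 to 118 CPM over the libraries, and YWHAE from 0.982 to 70.3 CPM. The mitochondrial pseudogene MTATP6P1 had 275 to 587 CPM in libraries where the mitochondrially encoded genes had no counts.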
